A study of Mus musculus with 8 samples.

How the data were processed

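RNA from purified retinal ganglion cells of postnatal day 8 mice, 4 NPC1-deficient and 4 wildtype libraries, was sequenced after preparation with an Illumina TruSeq kit that does not mark strand, per the labels' protocols. CASAVA 1.8.2, HTSeq 0.5.4p3, DESeq2 1.0.19 and the genome build mm10 are named in the submitters' processing notes without roles. The aligner and the annotation release are not given in the sources used here. The deposited table holds a normalized signal per gene and library, which is a read count divided by 1 size factor for each library, as the deposited values themselves show. No further filter by the authors is stated. Because counting did not use strand, reads of a gene and of an antisense partner cannot be told apart.

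The values of each library are whole multiples of its smallest step, so the whole reads could be recovered. All 199536 values (100%) came out whole within 1e-06 of a read. The recovered totals were 33030175, 37670261, 39793308 and 44050118 reads for wildtype 1 to 4, and 41875855, 37925751, 35416750 and 37049054 for NPC1-deficient 1 to 4. Mitochondrial genes took between 9.04% and 12.7% of the reads. A value of 0 allows up to 3 reads, which is a normalized value of 2.69 to 3.42 depending on the library, and this limit covers counting error only. Within groups, pairs of libraries differed by a chi-square of 4.54 to 54.8 per degree of freedom, so none was treated as deposited more than once.

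Libraries were grouped by title and description, which contradict a characteristics field that calls libraries 1 and 2 of both groups wildtype and libraries 3 and 4 homozygous. Libraries 1 and 2 against 3 and 4 are called the library sets. Genes with a mean normalized value of at least 10 were tested, which left 15386 and removed 9556. The values were taken as log2(value + 1), so fold changes of low genes are understated. NPC1-deficient and wildtype libraries were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no covariate, and Benjamini-Hochberg adjustment at 0.05. The level of Npc1 was also compared by an exact two-sided permutation test. The 16 pathway lists and 17 cell type lists were tested with limma camera at a preset correlation of 0.01 and adjusted as separate families. They were tested again with an estimated correlation and with fry. Of the camera calls, cholesterol synthesis, fatty acid synthesis and immediate early genes held with an estimated correlation, and the other 10 did not. The same 3 lists passed with fry, and the other 10 did not, with adjusted p values from 0.0951 to 0.227.

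Design, lists, and the rule for named genes were fixed before the data were examined. The rule named Npc1 and Npc2, up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold without overlap of the groups, up to 4 members of each pathway list with the smallest p, and up to 3 of each cell type list. Lbr, Egr2, Abca1, the Y-linked genes and the genes so marked in the closing section were chosen after their values were seen. Some genes that the rule names are not reported here. Gene positions came from GENCODE mouse release M21, in which 24471 of 24942 gene identifiers (98.1%) were found, and which is on the same build as mm10.

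Alternatives were pseudocounts of 0.5 and 5, no filter and a minimum of 50, quantile and upper-quartile scaling, robust variance moderation, the replicate number as a block, the library set as a term, each set alone, the groups of the characteristics field, and leaving out each library. On the recovered reads, the edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 were run as further alternatives. After the data were seen, fits without wildtype 1 and NPC1-deficient 1, and with the male RNA level, the microglial level or the rod level as terms, were added. The limma fit was tested on data simulated for this comparison over 15386 genes, with 50 genes changed at each size. It recovered 26% of genes changed by 0.35 on the log2 scale, 46% at 0.5, 82% at 1 and 98% at 2, and 11 of its 137 calls were unchanged genes. Limma camera called a simulated list of 20 genes raised by 0.35, and it called 11 of 200 random lists at an unadjusted 0.05. The simulated genes varied independently, so this does not test camera on correlated lists. In the data the estimated correlation of the lists ran from -0.29 (lens) to 0.95 (microglia), with 0.39 for cholesterol synthesis.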

Results

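RNA sequencing libraries were made from retinal ganglion cells, the neurons that send the optic nerve to the brain, of mice at postnatal day 8. The cells had been purified from dissociated retina by immunopanning, in which antibody-coated plates hold the wanted cells, and RNA was taken without a culture period. The comparison asks how loss of NPC1, the lysosomal membrane protein that exports cholesterol and is lost in Niemann-Pick disease type C, changes gene expression in this neuron. There were 4 libraries of NPC1-deficient mice and 4 of wildtype littermates. Library totals ran from 33030175 reads in wildtype 1 to 44050118 in wildtype 4, and 24942 genes were listed. The labels do not say whether each library came from separate animals, so p-values measure only the spread between these libraries.

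Npc1 (ENSMUSG00000024413, chromosome 18, 12189692 to 12236400, minus strand, mm10) was read first because it checks the labels. Its normalized read count was 787 ± 69.1 (SD, n = 4) in wildtype and 85.9 ± 36.0 (SD, n = 4) in NPC1-deficient libraries, 10.9% of the wildtype mean. The log2 fold change was -3.25 (SE 0.20, limma adjusted p = 3.23e-05), and an exact two-sided permutation test gave p = 0.0286, the smallest that 70 assignments allow. Every library titled NPC1-deficient lay between 8.40% and 17.8% of the wildtype mean, with NPC1-deficient 1 the highest at 140. A second label field calls libraries 1 and 2 of both groups wildtype and libraries 3 and 4 of both homozygous. Grouped by that field, Npc1 differed by -0.18 on the log2 scale (limma adjusted p = 0.951). Groups follow the titles and descriptions throughout. Within libraries 1 and 2 the log2 fold change of Npc1 was -2.87, and within libraries 3 and 4 it was -3.64. The count is of reads over the whole gene, and 4.5% of its exonic length is shared with Rmc1 on the opposite strand. Npc2, whose product hands cholesterol to NPC1 in the lysosome, had a log2 fold change of 0.08 (limma adjusted p = 0.995).

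**Figure D1:**
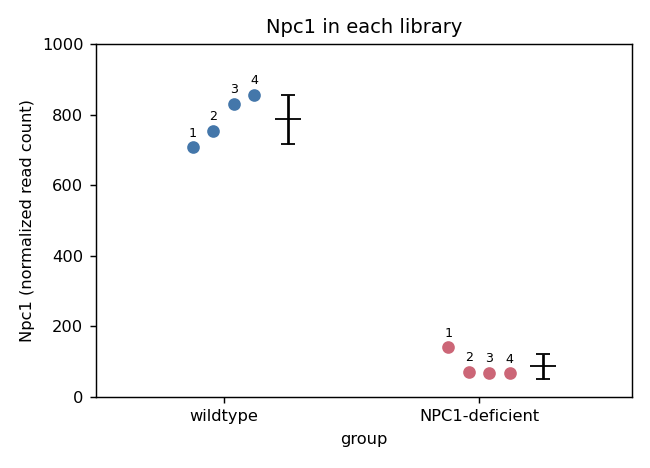
Normalized read count of Npc1 in each library, numbered by replicate, with the mean and SD of each group (n = 4) as a bar beside the points. The NPC1-deficient libraries lie between 66.1 and 140, all below the lowest wildtype library at 707.

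Genes of cholesterol synthesis were higher in NPC1-deficient cells. Of the 21 list members tested, all 21 had a positive fold change, with a median of 0.34 on the log2 scale. Over all genes tested 5 rose, and adjusted over the list alone 20 rose, the exception being Lbr at 0.18 (SE 0.10). Nsdhl, a sterol dehydrogenase, rose by 0.40 (SE 0.05, limma adjusted p = 0.0273), from 4386 ± 176 to 5785 ± 275 normalized reads (SD, n = 4). Fdps, which makes farnesyl diphosphate, rose by 0.48 (SE 0.06, limma adjusted p = 0.0273). Mvk and Mvd, enzymes of the mevalonate pathway, rose by 0.35 (SE 0.05) and 0.47 (SE 0.07), both at a limma adjusted p of 0.0312. The list as a whole moved up against other genes (limma camera adjusted p = 1.03e-30; adjusted p = 0.0253 with an estimated correlation). Its median was 0.29 within libraries 1 and 2 and 0.41 within libraries 3 and 4. With the level of rod markers as a term in the model, 9 members passed adjusted over the list alone, and the list median was 0.27. The mean log2 rod level was 8.1 to 9.4 in wildtype and 7.6 to 8.0 in NPC1-deficient libraries. It separates the groups, so this term is hard to tell from genotype. Reads of Fdps are uncertain in part, since 26.7% of its exonic length overlaps Gm43738.

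**Figure D2:**
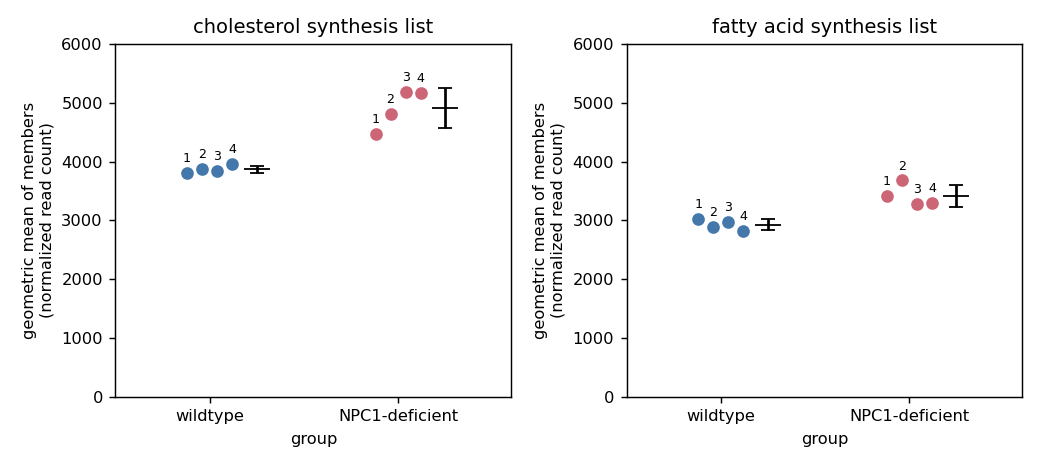
Geometric mean of the normalized read counts of the cholesterol synthesis and fatty acid synthesis lists in each library, on an axis from 0, with the mean and SD of each group (n = 4) as a bar beside the points. In both lists every NPC1-deficient library lies above every wildtype library.

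Fatty acid synthesis moved the same way, with a median log2 fold change of 0.22 over 13 genes (limma camera adjusted p = 8.01e-11; adjusted p = 0.0253 with an estimated correlation). Over all genes tested 1 member rose, Fads1, a desaturase of polyunsaturated fatty acids, by 0.28 (SE 0.04, limma adjusted p = 0.0312). Adjusted over the list alone 10 rose, among them the desaturase Scd1 by 0.46 and Fads2 by 0.37. The median was 0.26 within libraries 1 and 2 and 0.19 within libraries 3 and 4. With the level of microglial markers as a term, 3 members passed adjusted over the list alone, the list median was 0.16 and the list still passed. The mean log2 microglial level was 7.23, 8.85, 8.62 and 9.44 in wildtype 1 to 4 and 6.58 to 7.45 in NPC1-deficient libraries. Apart from wildtype 1 it separates the groups, so this term too is hard to tell from genotype.

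In the list of sterol sensing and lipoprotein uptake, none of 15 genes passed over all genes tested and 4 rose adjusted over the list alone. Among them were Lrp1, an endocytic receptor, by 0.37, the sterol carrier Stard4 by 0.37 and Insig1, which holds back the sterol-regulated transcription factors, by 0.33. The list median was 0.12 (limma camera adjusted p = 0.00495; adjusted p = 0.186 with an estimated correlation). Within libraries 3 and 4 alone its median was 0.03 (limma camera adjusted p = 0.356), and it was 0.0499 without NPC1-deficient 1 and 0.0691 without NPC1-deficient 2. Without both wildtype 1 and NPC1-deficient 1 the list did not pass (limma camera adjusted p = 0.0587). Of 14 genes of cholesterol efflux and oxysterols, 1 fell over all genes tested and 3 fell adjusted over the list alone. Apoe, which encodes an apolipoprotein, fell by 1.31 on the log2 scale (SE 0.21, limma adjusted p = 0.0482). The transporter genes Abca1 and Abcg1 fell by 1.63 and 0.40 adjusted over the list alone. The efflux list had a median of -0.03 and did not pass (limma camera adjusted p = 0.0648), but it passed without wildtype 1 (0.00219), NPC1-deficient 1 (0.0298) or NPC1-deficient 2 (0.0466). Leaving out single libraries moved its median between -0.0752 (without wildtype 1) and 0.0047 (without wildtype 4). The efflux list also passed within libraries 3 and 4 (limma camera adjusted p = 0.00588) and with quantile scaling (0.0497), where its median was 0.0026. Apoe fell alongside microglial markers, and with the microglial level as a term its log2 fold change was -0.64 (limma adjusted p = 0.229). Since that term is hard to tell from genotype, the source of the Apoe fall stays open.

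Immediate early genes, transcripts that neurons and other cells induce within minutes of a stimulus, were lower in NPC1-deficient libraries. All 13 had a negative fold change with a median of -0.62, 2 fell over all genes tested and 11 fell adjusted over the list alone (limma camera adjusted p = 1.63e-18; adjusted p = 0.0253 with an estimated correlation). The nuclear receptor gene Nr4a1 fell by 0.94 (SE 0.14) and the antiproliferative gene Btg2 by 0.64 (SE 0.10), both at a limma adjusted p of 0.0312. Egr1 fell by 0.52 and Egr2 by 2.10 adjusted over the list alone. The median was -0.34 within libraries 1 and 2 and -1.004 within libraries 3 and 4. With the microglial level as a term the median was -0.47 and 6 members passed adjusted over the list alone, and with the rod level as a term it was -0.57 with 10.

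Outside these lists, several further genes fell. Itgb5, an integrin subunit, fell by 1.10 (SE 0.12, limma adjusted p = 0.0103), from 447 ± 68.9 to 207 ± 20.2 normalized reads (SD, n = 4). Arhgap9, a GTPase-activating protein, fell by 2.48 from a low level of 23.996 ± 9.23 to 3.30 ± 0.728 (SD, n = 4). Pxdc1 fell by 1.74, with 10.5% of its exonic length shared with an antisense gene. Calb1, a calcium-binding protein also listed as a horizontal cell marker, fell by 0.84, and Trib1 and Pcp4l1 fell by 0.71 each. Markers of other cell types fell in the same libraries, and whether these falls lie in ganglion cells was not tested. With the microglial level as a term, which is hard to tell from genotype, 5 of the 16 genes called in the main fit passed.

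Markers of microglia, rods, cones, amacrine cells, bipolar cells and Müller glia were lower as lists in NPC1-deficient libraries at the preset correlation, but with an estimated correlation the adjusted p of each was 0.216. Pericyte markers were higher and ganglion cell markers close to even. Of 14 markers of microglia and macrophages, all 14 had a negative fold change and 13 fell adjusted over the list alone, with a median of -1.43 (limma camera adjusted p = 2.04e-13). Csf1r, the receptor microglia need to survive, fell by 1.89 and C1qc, a complement component, by 1.56 adjusted over the list alone. Rod markers had a median of -0.99 (limma camera adjusted p = 1.49e-12), and 13 of 16 fell adjusted over the list alone. The rod factor gene Nr2e3 fell by 1.10. Amacrine markers had a median of -1.01 (limma camera adjusted p = 5.63e-07), and 6 of 11 fell adjusted over the list alone. Among these Gad1, which makes the transmitter GABA, fell by 1.76, Slc32a1 fell by 1.68 and Tfap2b fell by 1.45. Of the exonic lengths of Slc32a1 and Csf1r, 24.9% and 15.1% overlap opposite-strand genes. Cone markers had a median of -0.88 with 2 of 5 falling adjusted over the list alone (limma camera adjusted p = 0.00968). Bipolar markers had a median of -0.51 with none of 11 passing singly (limma camera adjusted p = 0.00968). The Müller glia list had a median of -0.28, with Slc1a3 falling by 0.81 adjusted over the list alone (limma camera adjusted p = 0.0201). Pericyte and fibroblast markers had a median of 0.37 over 5 genes, none passing singly (limma camera adjusted p = 0.0491). Ganglion cell markers had a median of 0.06, none of 17 passing singly (limma camera adjusted p = 0.0411). For these 2 lists as well the adjusted p was 0.216 with an estimated correlation. With fry the 8 lists had adjusted p values between 0.0951 and 0.227. No gene of these lists passed over all genes tested.

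The microglial difference depended on the library. The geometric mean of the microglial markers was 149, 460, 391 and 694 normalized reads in wildtype 1 to 4, and 174, 158, 167 and 94.95 in NPC1-deficient 1 to 4. The median log2 fold change was -0.66 within libraries 1 and 2 and -2.11 within libraries 3 and 4. The same values were -1.16 and -0.71 for rods and -1.31 and -0.71 for amacrine cells. In a fit of libraries 3 and 4 alone, with genes filtered anew, cones (-0.34, limma camera adjusted p = 0.458), Müller glia (-0.0994, 0.555) and ganglion cells (0.0051, 0.496) did not pass. Over the cone markers of the main fit the median within these libraries was -0.21. Within libraries 1 and 2 bipolar cells (-0.24, limma camera adjusted p = 0.276) and ganglion cells (0.0914, 0.0886) did not pass. Without wildtype 1 the cone and bipolar lists no longer passed (limma camera adjusted p = 0.0671 for each), nor did Müller glia (0.0720). Their medians were then -0.61 for cones, -0.18 for bipolar cells and -0.12 for Müller glia. Without NPC1-deficient 3 the bipolar median was -0.31 and the Müller median -0.0806, and both lists passed. Without wildtype 3 or NPC1-deficient 2 none of the cone markers passed singly and without wildtype 1 there was 1, while 3 bipolar markers passed without NPC1-deficient 1. Slc1a3 did not pass without wildtype 3 or NPC1-deficient 1, where 0 Müller markers did, and 2 passed without wildtype 4. The Müller list also failed without NPC1-deficient 1 (0.0592) or NPC1-deficient 2 (0.0567). The ganglion cell list failed without wildtype 2 (limma camera adjusted p = 0.0617), wildtype 3 (0.0876), NPC1-deficient 1 (0.219) or NPC1-deficient 2 (0.0776). The pericyte list failed without wildtype 2 (limma camera adjusted p = 0.0657), wildtype 3 (0.0876), wildtype 4 (0.0815), NPC1-deficient 1 (0.358) or NPC1-deficient 2 (0.126), and its median was 0.19 both without wildtype 3 and without NPC1-deficient 1.

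**Figure D3:**
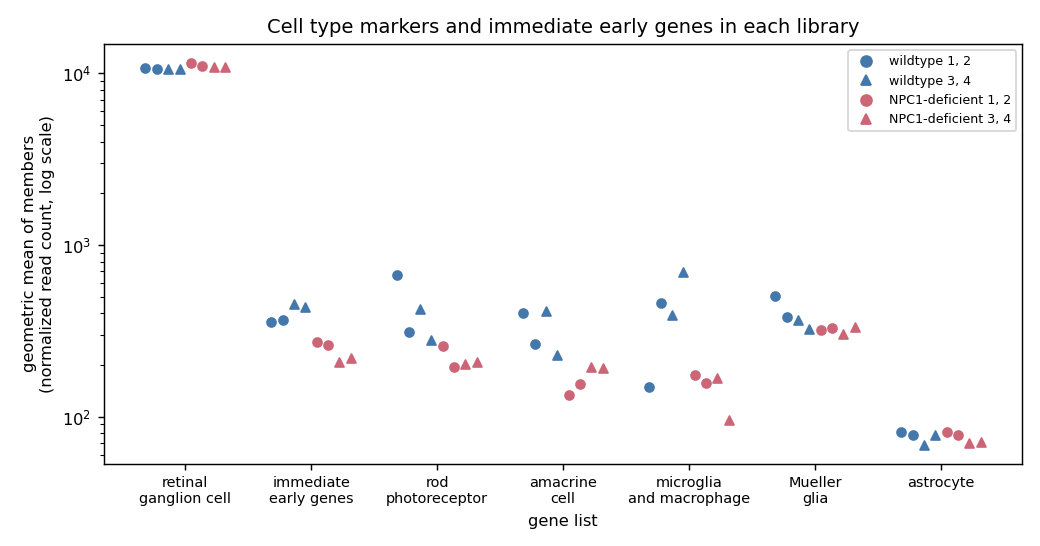
Geometric mean of the normalized read counts of 7 gene lists in each library, on a log axis, with circles for libraries 1 and 2 and triangles for libraries 3 and 4. Microglial markers in wildtype 1, at 149, lie within the NPC1-deficient range of 94.95 to 174.

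The sex of the mice also differed between libraries, and in part with genotype. Xist, made from the inactive X chromosome of females, stood at 595 normalized reads in wildtype 1, 18.2 in wildtype 2, 238 in wildtype 3 and 164 in wildtype 4. In NPC1-deficient 1 to 4 it stood at 68.1, 3.0, 1.1 and 0. The sum of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 45.6 in wildtype 1 and between 1241 and 3093 in the other wildtype libraries, against 2597 to 3788 in NPC1-deficient libraries. Wildtype 3 and 4 held Xist together with Y-linked RNA, so each held RNA of both sexes. NPC1-deficient 1 also showed both, with Xist at 68.1 and a Y-linked sum of 2597, and wildtype 2 did so weakly, with Xist at 18.2. Xist averaged 254 in wildtype and 18.0 in NPC1-deficient libraries, so effects of sex and genotype cannot be fully told apart. As a list the sex-linked genes had a median of 2.14 and did not pass (limma camera adjusted p = 0.127). They passed without wildtype 1, with a median of 0.81 (limma camera adjusted p = 0.0258), and without wildtype 2, with a median of 2.85 (0.0464), and also within libraries 3 and 4, with a median of 1.34 (0.00156).

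Genes of the lysosome, where NPC1 resides, did not move as a group. None of 35 passed, 20 had a positive and 15 a negative fold change, and the median was 0.01 (limma camera adjusted p = 0.775), while the mean lay at -0.0047. Without wildtype 1 there was 1 that passed adjusted over the list alone. The median was 0.07 within libraries 1 and 2 (limma camera adjusted p = 0.0423) and -0.07 within libraries 3 and 4 (0.144). With the microglial level as a term the lysosomal median was 0.11 (limma camera adjusted p = 3.23e-05), and with the rod level -0.04 (0.0111). Sphingolipid metabolism had a median of 0.02 over 19 genes (limma camera adjusted p = 0.302), autophagy 0.03 over 20 (0.461), antioxidant response 0.04 over 16 (0.302) and oxidative phosphorylation 0.01 over 24 (0.744). No member of these 4 lists passed. Oxidative phosphorylation passed without NPC1-deficient 2, with a median of 0.0529 (limma camera adjusted p = 0.00493), and with the microglial level as a term, with a median of 0.0612 (0.0330). The antioxidant list also passed with that term, with a median of 0.0999 (limma camera adjusted p = 0.0156). Axonal cytoskeleton genes had a median of 0.06 with 14 of 16 higher (limma camera adjusted p = 0.0648), and the list passed without wildtype 1 (0.0202), NPC1-deficient 2 (0.0377) or NPC1-deficient 3 (0.0336), and within libraries 3 and 4 (0.0379).

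In the interferon and MHC class I list 2 of 15 genes rose adjusted over the list alone, Usp18 by 1.64 and H2-D1 by 0.23. Its median was 0.23 (limma camera adjusted p = 0.00128; adjusted p = 0.186 with an estimated correlation). The list did not pass within libraries 3 and 4 (limma camera adjusted p = 0.356) or without both wildtype 1 and NPC1-deficient 1 (0.102). Without NPC1-deficient 1 none of its members passed, without NPC1-deficient 2 or wildtype 3 there was 1, and without wildtype 1 there were 3. Axon injury genes had a median of 0.0012 (limma camera adjusted p = 0.302), and 1 member, Atf3, fell by 1.81 adjusted over the list alone. No axon injury member passed without wildtype 2, wildtype 3, NPC1-deficient 2 or NPC1-deficient 3, the number past being 0 each time, and 4 passed without wildtype 4. Among p53 targets, with a median of 0.02 (limma camera adjusted p = 0.933), Pmaip1 fell by 1.95 adjusted over the list alone. Among synaptic vesicle genes, with a median of 0.0031 (limma camera adjusted p = 0.803), Rims1, a scaffold of release sites, fell by 1.70 adjusted over the list alone, and its log2 fold change was -2.33 within libraries 1 and 2 and -1.07 within libraries 3 and 4. Without NPC1-deficient 1, 3 synaptic vesicle genes passed adjusted over the list alone, and the list passed downward with a median of -0.0498 (limma camera adjusted p = 0.0293). It passed upward within libraries 1 and 2, with a median of 0.11 (limma camera adjusted p = 0.0193), and downward within libraries 3 and 4, with a median of -0.16 (0.000206). Endoplasmic reticulum stress had a median of 0.01 and no member passed (limma camera adjusted p = 0.869). In these last 4 lists the median was above 0 while the camera test pointed down.

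The remaining cell type lists did not pass with all 8 libraries and no further term. Their medians were -0.39 for 2 horizontal cell markers (limma camera adjusted p = 0.124), 0.07 for 4 astrocyte markers (0.652) and -0.11 for 7 endothelial markers (0.116), of which Kdr fell by 0.86 adjusted over the list alone. Without wildtype 1, wildtype 3, NPC1-deficient 1 or NPC1-deficient 2, 0 endothelial markers passed, and the list passed without wildtype 2 (limma camera adjusted p = 0.0490). The endothelial median was -0.20 without wildtype 2, -0.19 without NPC1-deficient 1, -0.0647 without NPC1-deficient 3 and -0.0304 without wildtype 4. The astrocyte mean was -0.0245, opposite in sign to its median. Oligodendrocyte markers had a median of -0.05 (limma camera adjusted p = 0.252), erythrocyte markers -0.96 (0.222), cycling cell markers -0.03 (0.575), lens markers -0.36 (0.124) and pigment epithelium markers 0.04 (0.691). The lens list passed without wildtype 3 (limma camera adjusted p = 0.0441) or NPC1-deficient 3 (0.0125). The erythrocyte list passed without NPC1-deficient 3, with a median of -1.53 (limma camera adjusted p = 0.0393). The lens median was -0.61 without NPC1-deficient 1 and -0.22 without wildtype 2. In a fit of libraries 1 and 2 alone, with genes filtered anew, the erythrocyte list passed with a median of -2.92 (limma camera adjusted p = 0.00795) and the cycling cell list with -0.26 (0.00638). Over the 2 erythrocyte markers of the main fit the median was -2.64 within libraries 1 and 2 and 0.72 within libraries 3 and 4.

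In all, 16 of 15386 tested genes passed a limma adjusted p of 0.05, 6 higher and 10 lower, and in all 16 the groups did not overlap. Without overlap were 4.27% of all tested genes, against 2.86% by chance. At an unadjusted p under 0.05 there were 1040 genes, with 769 expected by chance. The edgeR quasi-likelihood test on the recovered reads called the same 16 genes, and DESeq2 called 246, 48 higher and 198 lower, with all 16 among them. On simulated data 28 of 166 DESeq2 calls were unchanged genes, against 11 of 137 for limma. With the library set as a term limma called 99 genes, all 16 among them, and it called 57 within libraries 1 and 2 and 335 within libraries 3 and 4. Without wildtype 1 and NPC1-deficient 1, the libraries that stood apart in Xist and Npc1, it called 170, 29 higher and 141 lower, which included 15 of the 16. With the microglial level as a term it called 76 genes and with the rod level 95, including 5 and 4 of the 16.

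Every single library moved the count by over 1.5 times. It was 144, 4, 5 and 35 without wildtype 1, 2, 3 and 4, of which 16, 3, 3 and 15 were among the 16. Without NPC1-deficient 1, 2, 3 and 4 it was 26, 4, 2 and 33, of which 9, 4, 2 and 14 were among the 16. Npc1 and Itgb5 passed in all 8 of these fits, while the other 14 genes failed in some. Cholesterol synthesis had 19 to 21 members past the threshold adjusted over the list alone in each of them.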

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

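The tests of a common share of other cells, of carry-over of each cell type, of the Npc1 excess in NPC1-deficient 1, and of ganglion cell share and depth between the library sets were chosen only after the results were seen. Dixon's test was applied to 234 groups of 4 libraries and 12 held a library far from the other 3, where chance alone gives about 11.7 (1 in 20). The critical ratio of gap to range was 0.829.

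Among single genes, NPC1-deficient 1 was highest for Npc1 (ratio 0.923), Pmaip1 (0.891) and Gngt1 (0.834). Wildtype 3 was highest for Nr4a1 (0.867) and lowest for Txnrd1 (0.874). NPC1-deficient 3 was lowest for Olig1 (0.893) and highest for Dct (0.891). Wildtype 1 was highest for Trib3 (0.834) and Hbb-bs (0.891). Among list means, NPC1-deficient 4 was lowest for the interferon list (0.856) and for microglia (0.841), and wildtype 1 was lowest for the sex-linked genes (0.912).

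The lower markers of microglia, rods and amacrine cells in NPC1-deficient libraries are a pattern that a biological and several technical explanations could give. A single lower share of all other cells would lower their markers alike. The microglial median differed from that of Müller glia by -1.16 on the log2 scale (SE 0.165). That SE is over list members, which vary together, and leaves out the spread between libraries. These medians were -0.66 and -0.31 within libraries 1 and 2, and -2.11 and -0.0994 within libraries 3 and 4. The gap changed with the library set, so this comparison of medians does not decide. In wildtype 1 to 4 the geometric mean was 149, 460, 391 and 694 for microglial markers and 668, 311, 421 and 279 for rod markers. These run in opposite order, which argues against a single share of all other cells among the wildtype libraries. In NPC1-deficient 1 to 4 the means were 174, 158, 167 and 94.95 for microglia and 257, 195, 202 and 209 for rods, without such an order. A lower share as 1 part of the fall is not excluded. Scaling is argued against, since quantile or upper-quartile scaling shifted the medians of the 3 lists by at most 0.0885. Carry-over of each cell type that varies between preparations remains a candidate explanation: within groups the residuals of list members correlated at a median of 0.968 for microglia, 0.721 for rods and 0.453 for amacrine cells, above the 95th percentile of 1000 random lists (0.155, 0.115 and 0.158), but so did cholesterol synthesis (0.471) and immediate early genes (0.378), so the measure is not particular to carry-over. An effect of genotype on these cells in the retina stays open and was not tested, because immunopanning should remove them and the libraries hold no count of cells.

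Npc1 in NPC1-deficient 1 was 140 normalized reads against 66.1 to 70.05 in the other 3 libraries of its group, from 154 reads (exact Poisson 95% interval 131 to 180). RNA of an NPC1-deficient female is argued against as the source of this Npc1, which lay 8.08 wildtype SDs above the mean of the other 3 on the log2 scale (excess 1.03, SD 0.13 in wildtype and 0.0418 in the other 3). RNA of wildtype female cells may be present: the excess of Npc1 would need a share of 9.99% and that of Xist 11.2%, a ratio of 1.13. The Xist share takes wildtype 1, at 595, as the level of female cells, so the closeness of these shares rests on that library. The Y-linked sum was 2597 in NPC1-deficient 1 against 3479 to 3788 in the other 3, a larger gap than either share. Whether such RNA came from reads of wildtype 1 cannot be told apart from other female cells. Only 4 genes stood far enough above the other 3 NPC1-deficient libraries in wildtype 1. Their excess in NPC1-deficient 1 was a median of 16.8% of their wildtype 1 level, from 12% to 71.1%. They were not particular to wildtype 1: in wildtype 3 Gm26870 stood at 102 and Cabp5 at 28. No biological explanation was tested, and leaving this library out moved the log2 fold change of Npc1 to -3.51.

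Libraries 1 and 2 differed from libraries 3 and 4, across genotypes, in 271 genes, 46 higher and 225 lower in 3 and 4. A lower share of ganglion cells in libraries 3 and 4 would lower their markers, but that list differed by -0.0094 on the log2 scale (SE 0.0526), where -0.18 was the bound, and no cell type list passed between the sets (0 by limma camera). Depth is argued against by overlapping totals, with a ratio of mean reads of 1.04. Transcript length and GC content stay open and cannot be told apart from other causes: after their trends were removed 155 of 270 genes still differed, 138 of them shared, and the median of the lower genes went from -0.37 to -0.29, while the genotype count went from 16 to 36. The genes lower in 3 and 4 had a median length of 6618 bases against 3266 for all tested genes, and the labels name no batch.

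Of the 35 splits of the 8 libraries into groups of 4, 2 gave at least as many genes as the 16 of the real split, so chance is not excluded for that count. The other one was the split by library set, with 271 genes, several times the real count, which points to a structure of the samples; with the set as a term the genotype count was 99. For cholesterol synthesis members adjusted over the list alone, 1 of 35 splits, the real one, gave 20 and the highest other gave 13. That is the smallest share that 35 splits allow. It lies under 0.05 but was not adjusted over the 4 counts compared, so it does not exclude chance by itself. For pathway lists 7 splits gave at least the real 5, the highest other 8, and chance is not excluded. For cell type lists 1 split, the real one, gave 8 and the highest other 7, for camera at the preset correlation only. This is the same smallest share with the same limit, and the margin is narrow. With an estimated correlation all 8 lists had an adjusted p of 0.216, and without wildtype 1 the cone, bipolar and Müller lists did not pass (limma camera adjusted p = 0.0671, 0.0671 and 0.0720).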

How the results depend on the processing

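The fits without wildtype 1 and NPC1-deficient 1, and with male RNA, microglial or rod level as terms, were chosen only after the results were seen. Npc1 and the cholesterol synthesis list kept direction and call in every alternative run except the groups of the characteristics field. Npc1 lay between -2.87 and -3.64 in the others, and leaving out single libraries put the cholesterol median at 0.31 to 0.36. Causes were not tested except where fewer genes or libraries were fitted. On simulated data limma recovered 26% of changes of 0.35 and DESeq2 40%, so changes of that size are often missed.

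Of genes passing (16; 6 higher, 10 lower), leaving out single libraries gave 2 to 144, with 0 to 17 higher and 2 to 131 lower. A minimum of 50, which tests fewer genes, gave 10 with 5 lower. The library set as a term gave 99 (28 higher, 71 lower). Libraries 1 and 2 alone gave 57 (49 lower), and 3 and 4 alone 335 (97 higher, 238 lower). DESeq2 gave 246 (48 higher, 198 lower), with 11 adjusted p-values not given. Without wildtype 1 and NPC1-deficient 1 there were 170 (29 higher, 141 lower), and with set and male RNA level 144 (18 higher, 126 lower). The microglial term gave 76 (67 lower) and the rod term 95 (1 higher, 94 lower). No filter gave 21, quantile scaling 14, upper-quartile scaling 17 and robust moderation 12. The higher share was 37.5%, and 35.7% and 35.3% under the other scalings.

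With the replicate number as a block the count was 34 (26 lower), 14 of them shared with the 16. Same-numbered libraries did not deviate together across genes (correlations of -0.017, -0.033, -0.023 and -0.066), and no library correlated best with its own number. Such correlations over all genes cannot exclude that same-numbered libraries share something, since 271 genes differed between the library sets.

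Grouping by the characteristics field gave 271 genes (46 higher, 225 lower) and 0 cholesterol synthesis members. Under it Npc1 was -0.18 and the cholesterol median 0.0750. Log2 fold changes turned for Itgb5 (0.25), Arhgap9 (0.23), Pxdc1 (0.21), Trib1 (0.0787), Fads1 (-0.00269), Nr4a1 (0.30), Btg2 (0.22), Pcp4l1 (0.11), Calb1 (0.12) and Apoe (0.23). List medians changed sign for fatty acid synthesis (-0.0122), immediate early genes (0.0137), ganglion cells (-0.00941), amacrine cells (0.0553), microglia (0.31) and pericytes (-0.17). The sterol sensing median stayed above 0 (0.0207) while its camera test pointed down. Oxidative phosphorylation (0.0710, limma camera adjusted p = 0.0154) and synaptic vesicle release (-0.11, 0.0285) passed. Adjusted over the list alone, 7 axonal cytoskeleton, 6 ganglion cell, 3 endoplasmic reticulum stress and 2 sphingolipid members passed, where none did by title.

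Lysosome genes passed within libraries 1 and 2 (0.0708) and with the microglial term (0.11), and turned with the rod term (-0.0370). Synaptic vesicle genes passed upward within libraries 1 and 2 (0.11, limma camera adjusted p = 0.0193) and downward within 3 and 4 (-0.16, 0.000206). The pericyte median was -0.16 in the fit of libraries 3 and 4 alone, which filtered genes anew. Over the 5 pericyte markers of the main fit it did not change sign within these libraries (0.37). The microglial term left the microglial median near 0 (-0.0124), as its construction implies, with the camera test pointing up. The rod term, whose level separates the groups, left 9 cholesterol synthesis members. Under it the rod median lay near 0 (0.0153), as its construction implies. Medians also changed sign for interferon (-0.0351), cones (0.0491), bipolar cells (0.0904), Müller glia (0.0406) and sex-linked genes (-1.68).

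Further lists changed call, with limma camera adjusted p in parentheses. Without wildtype 1 and NPC1-deficient 1 the calls of sterol sensing (0.0587), interferon (0.102), cones (0.0611), Müller glia (0.158), ganglion cells (0.182) and pericytes (0.473) ended, and efflux passed (0.000946). A minimum of 50 ended the calls of bipolar cells (0.0810) and Müller glia (0.0503), and efflux passed (0.0401). Quantile scaling ended that of ganglion cells (0.328), and the set term that of pericytes (0.0798). With the replicate block the lens list passed (0.0458). Set and male RNA terms ended the calls of interferon (0.250), ganglion cells (0.116), cones (0.132), bipolar cells and Müller glia (0.269 each) and pericytes (0.152), and efflux (0.000807) and axonal cytoskeleton (0.0207) passed. The microglial term ended those of sterol sensing (0.0930), ganglion cells (0.142) and pericytes (0.136), and erythrocytes (0.0230) and sex-linked genes (0.000169) passed. The rod term ended those of amacrine (0.275), ganglion cells (0.215) and pericytes (0.175), and efflux (0.00311) and axonal cytoskeleton (0.0179) passed.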

Other observations

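All comparisons in this part, and all its genes but Rims1 and Gad1, were chosen only after the values were seen, and no test was planned for them. The chemokine genes Ccl3, Ccl4 and Ccl9 had log2 fold changes of -2.52, -2.65 and -2.85, the apolipoprotein gene Apoc1 -2.25 and the myeloid transcription factor gene Cebpa -1.85, each at a limma adjusted p of 0.0679, above the threshold. Ccl4 stood at 169, 614, 465 and 1146.5 in wildtype 1 to 4, in the order of the microglial markers (149, 460, 391 and 694). Ccl9 stood at 1 to 3.6 in NPC1-deficient libraries, near the limit that a value of 0 allows. Whether these falls lie in ganglion cells was not tested. The aldehyde dehydrogenase genes Aldh1a1 and Aldh1a7 had log2 fold changes of 0.66 and 0.47 (limma adjusted p = 0.0700 and 0.0631), also above the threshold.

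Rims1, listed as a gene of synaptic vesicle release, varied 8.45-fold between the highest and the lowest library, and Gad1, an amacrine marker, varied 8.88-fold. The ratio of Rims1 to Gad1 stayed between 8.32 and 12.6 in all 8 libraries. Rims1 was the more abundant gene of the pair, at 11844 ± 3539 normalized reads in wildtype and 3949 ± 2082 in NPC1-deficient libraries (SD, n = 4).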
